A study of Saccharomyces cerevisiae W303 with 3 samples.

How the data were processed

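H2A.Z ChIP-seq was analysed in 3 libraries of S. cerevisiae W303: wild type, hst3 hst4 deletion and H3K56Q. Per the labels' protocols, cells were fixed in 1% formaldehyde, chromatin was cut with micrococcal nuclease, extract of 100 ml of culture was precipitated with 6 µl of antibody to Htz1, and libraries were amplified by PCR. CASAVA 1.7.0 is named in the submitters' processing notes. The aligner, its settings for repeated sequence and the genome build are not given in the sources used here. Groups were taken from the genotype labels.

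The deposited values are a coverage signal per base pair, normalised by the authors. Checked on the tables, every library has a mean of 1 and each value is a whole multiple, within 1e-06, of the smallest value above 0. That step was taken as 1 read, which gives the mean coverage. The length covered by a read was taken as the lag at which the first difference of the coverage on chromosome 4 was most negatively correlated with itself: 90 bp in wild type, 50 bp in the deletion and 54 bp in H3K56Q. Read numbers are coverage divided by that length, an approximation. Why the lengths differ is not stated in the labels. Wild type, with the longest reads, is smoothed most by them. Read length therefore separates wild type from both mutants, and its effect cannot be told from theirs. Smoothing to a common extent makes the widths equal, but how reads were placed on their fragments is not given.

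Analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Each library was divided by its mean outside the high-copy segment of chromosome 12, where the mean of the 3 libraries exceeded 10, and 10 kb on each side. Stretches of 100 bp or more at 0 in any library, with 200 bp around them, that segment, and segments of at least 800 bp in which 1 library lay below 0.4 of another were left out, 6.83% of positions in all. To find features, each track was smoothed with the read lengths of the other libraries, so that all shared a kernel. Regions were runs of the mean of the 3 libraries at 1.5 or more, joined over gaps of up to 300 bp and at least 150 bp long. Peaks were local maxima with a prominence of 0.1, at least 100 bp apart, measured over 147 bp. Pairs were neighbouring peaks of level 1.5 or more with a trough at or below 0.5 of the lower flank. Values are means of the scaled tracks without that smoothing, except for the troughs and the profile around them. Log2 ratios used a pseudocount of 0.05.

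Before the data were examined, the comparison was designed on windows at gene starts, gene bodies, fixed gene lists and named genes. That design was not run, because it needs gene positions in the build of the tables. From the R64 gene table the text gives only the chromosome and length of genes that the labels name or imply. While the data were explored, R64 gene positions had also been laid over the tracks, at HST3, HST4, the H3-H4 gene pairs and other genes, although the builds could not be matched. No value given comes from that, but the search for segments was written after it. Segments, regions, peaks and pairs, all their thresholds and the windows of the mean profile were chosen after seeing the data. Scaling, pseudocount and the rule for named items were kept and applied to regions: over 20 kb from an end, level at or above the median, the same sign in both mutants, and the 8 lowest and 8 highest ratios of each mutant. Centromeres, tRNA genes and mitochondrial DNA were not analysed here.

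No test between groups was possible with 1 library in each. Intervals of ratios are exact binomial intervals of the estimated reads, and those of medians come from 100 Poisson draws. The region code was tested on simulated data from 8 chromosomes, in which 200 regions were changed and 1738 were then called. For the deletion against wild type, all 44 called regions set to a fold of 0.5 and all 50 set to 2 passed 1.5-fold, as did 14 of 50 set to 1.5 and 0 of 1544 left unchanged. Alternatives tried were the values as deposited, other pseudocounts, the highest smoothed point, a filter on level, leaving out chromosome ends and, added after seeing the data, other scalings, region definitions and a common read extent.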

Results

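H2A.Z is the histone H2A variant that the SWR-C remodelling enzyme places into nucleosomes, often on either side of nucleosome-depleted promoters. Its distribution was measured by ChIP-seq with an antibody to Htz1, the budding yeast H2A.Z, on chromatin cut with micrococcal nuclease. The study asked where H2A.Z lies when acetylation of lysine 56 of histone H3 is constitutive. Acetylation of that lysine is removed by the deacetylases Hst3 and Hst4, and its replacement by glutamine (H3K56Q) mimics the acetylated state. There were 3 Saccharomyces cerevisiae cultures of W303 type, with 1 library in each group: wild type, a strain lacking HST3 and HST4, and H3K56Q. There are no replicates, so values are set side by side without a test. No input or nucleosome library is among them, so H2A.Z signal is not corrected for nucleosome occupancy, digestion or DNA copies. The deletion strain was grown at 23 °C and the other strains at 30 °C, so temperature cannot be separated from that genotype.

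Each table listed 12070792 positions on 16 chromosomes. Mean coverage per position was 88.3 reads in wild type, 30.4 in the deletion and 55.95 in H3K56Q, which corresponds to about 11.8, 7.34 and 12.5 M reads. Signal below is relative to a library mean of 1. Intervals are 95% and cover counting error only, since reads copied by PCR without molecular identifiers are not independent molecules. Positions are those of the deposited tables, whose genome build is not given in the sources used here, so no gene is assigned to a position.

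Segments with low signal were examined first, since the deleted genes should lack signal. In the deletion library 2 segments of at least 800 bp lay below 0.4 of wild type. The segment on chromosome 4 from 842201 to 843450 had a mean signal of 1.18 in wild type, 0.257 in the deletion and 1.27 in H3K56Q. The segment on chromosome 15 from 378151 to 379650 had 0.724 in wild type, 0.19 in the deletion and 0.737 in H3K56Q. In the R64 gene table HST4 is on chromosome IV with a length of 1113 bp and HST3 on chromosome XV with 1344 bp, and these segments were 1250 and 1500 bp long. The search for segments was written after tracks at these genes had been viewed with R64 positions, so the match of chromosome and length is not an independent check of the labels. Some signal remained in both. In the inner 850 bp of the chromosome 4 segment the deletion library kept 14.2% of the wild-type signal (exact binomial interval 11.2 to 18.1), and in the inner 1100 bp of the chromosome 15 segment 17.7% (13.2 to 23.0).

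**Figure D1:**
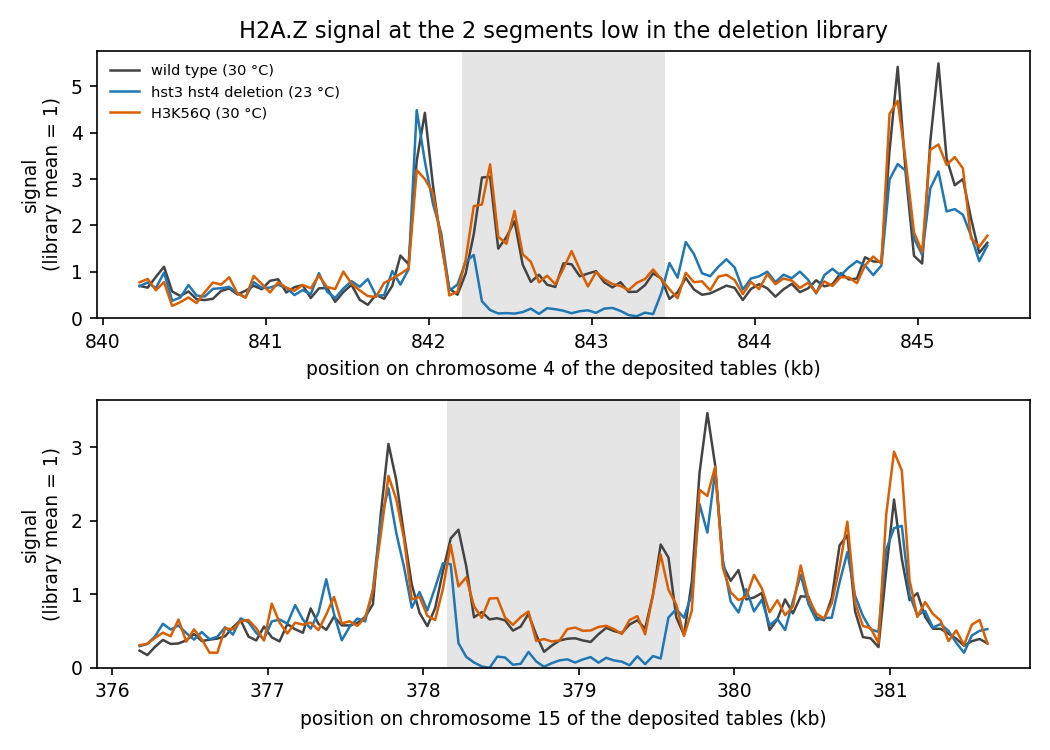
Mean signal in 50-bp windows (y axis, library mean of 1) against position in kb for the 3 libraries, with the 2 segments low in the deletion library shaded. Over the inner part of the shading the deletion averages 0.148 on chromosome 4 and 0.0897 on chromosome 15, against 1.04 and 0.507 in wild type and 1.11 and 0.582 in H3K56Q.

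H3K56Q had 5 such segments against wild type, on chromosomes 2, 4, 4, 10 and 14. On chromosome 2, from 255001 to 257100, the mean was 0.536 in wild type and 0.124 in H3K56Q. On chromosome 14, from 577151 to 578050, it was 0.659 and 0.139. These chromosomes carry the H3-H4 gene pairs HHT1-HHF1 (II) and HHT2-HHF2 (XIV) in the R64 gene table. Tracks at those genes had also been viewed with R64 positions before these segments were picked out for mention, and no segment is assigned to a gene here. The longest, on chromosome 4 from 1155851 to 1159800, had 1.39 in wild type, 1.13 in the deletion and 0.119 in H3K56Q. Over the inner parts of the 5 segments together H3K56Q kept 12.9% of the wild-type signal (12.1 to 13.8), with single segments from 8.69 to 31.8%. In the other direction, wild type lay below 0.4 of the deletion in 19 segments, 25850 bp in all, and below 0.4 of H3K56Q in 42, 80200 bp in all.

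H2A.Z-rich regions stood out less from the rest of the genome in both mutants than in wild type. Regions were stretches where the mean of the 3 libraries reached 1.5. There were 3927, of median length 508 bp, over 22.3% of the positions used. Mean signal inside them was 2.23 in wild type, 2.06 in the deletion and 2.08 in H3K56Q. Outside them it was 0.724, 0.77 and 0.758, but with each library scaled to a mean of 1 a lower mean inside brings a higher mean outside, so these are not separate findings. The ratio of inside to outside, which needs no scaling, was 3.08 in wild type, 2.67 in the deletion and 2.75 in H3K56Q. The regions held 46.8% of the signal in wild type, 43.4% in the deletion and 44.1% in H3K56Q.

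Per region, the median log2 ratio to wild type was -0.12 in the deletion (quartiles -0.22 and -0.015) and -0.10 in H3K56Q (-0.21 and 0.017). The counting intervals of these medians were -0.12 to -0.12 and -0.10 to -0.10. In the deletion 3061 regions were lower and 866 higher, and in H3K56Q 2826 and 1101. The median lay below 0 on each of the 16 chromosomes in both mutants. Set against positions within 2 kb that belong to no region, a ratio that needs no scaling between libraries, the median region stood 2.77-fold above its surroundings in wild type, 2.40-fold in the deletion and 2.49-fold in H3K56Q. That contrast was smaller than in wild type at 89.5% of regions in the deletion and 83.2% in H3K56Q.

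Few regions differed by 1.5-fold or more, among those called without the segments in which 1 library lay below 0.4 of another. In the deletion 14 were lower and 15 higher, and in H3K56Q 72 were lower and 52 higher, where draws with counting error alone gave 0. With those segments kept, the counts were 14 and 16 in the deletion and 74 and 59 in H3K56Q. The split depends on the scaling. With the median outside regions set equal, 60 were lower and 6 higher in the deletion and 119 and 38 in H3K56Q, and the medians were -0.24 and -0.18. When regions were compared by their highest smoothed point in place of their mean, 363 and 312 passed.

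Across peaks, the log2 ratios fell as the level of H2A.Z rose. Among 31790 peaks, each measured over 147 bp, the 7057 of level 0.5 to 0.75 had median log2 ratios of 0.093 in the deletion and 0.053 in H3K56Q. The 3750 peaks of level 2 to 3 had -0.17 and -0.13. The 973 peaks of level 4 or more had -0.25 and -0.23, and 93.8% and 90.3% of them were lower than in wild type. Classing peaks by the library of the other mutant, so that neither library of a ratio sets the class, gave -0.24 in the deletion and -0.22 in H3K56Q at level 4 or more. Region means did not fall as steadily. Regions of level 1.5 to 2 had medians of -0.088 in the deletion and -0.070 in H3K56Q. Those of level 2.5 to 3 had -0.17 and -0.14, and those of level 3 to 4 had -0.16 and -0.14.

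**Figure D2:**
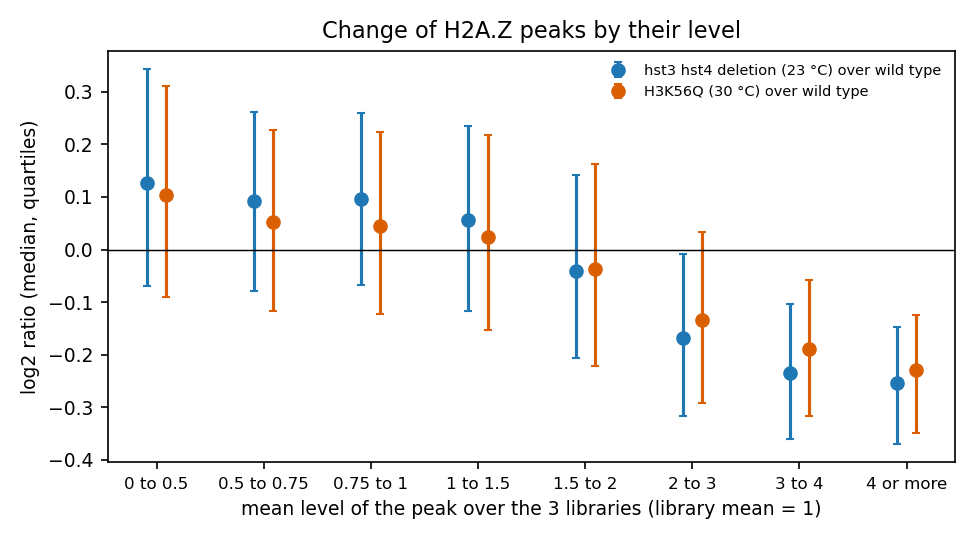
Median log2 ratio to wild type (y axis, points; bars span the quartiles of the peaks) by mean level of the peak over the 3 libraries (x axis). The medians go from 0.13 and 0.10 below level 0.5 to -0.25 and -0.23 at level 4 or more, in the deletion and H3K56Q.

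H2A.Z commonly occupies the nucleosomes that flank a nucleosome-depleted gap. Without gene positions, such places were taken as 2363 pairs of neighbouring peaks 180 to 450 bp apart with a trough between them. The higher flank had a median log2 ratio of -0.22 in the deletion and -0.19 in H3K56Q, and the lower flank -0.18 and -0.12. The trough had higher signal, with 0.30 and 0.19. The trough stood at 27.8% of its flanks in wild type, 39.7% in the deletion and 35.7% in H3K56Q. The next peak outward of the higher flank, at 562 pairs, had -0.046 and -0.029.

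Averaged over 2293 of these pairs with the tracks smoothed to a common read extent, the flanks lay at the same places in the 3 libraries, 150 bp and -130 bp from the trough. The higher flank reached 4.12 in wild type, 3.18 in the deletion and 3.31 in H3K56Q, and the lower flank 2.93, 2.34 and 2.49. Wild type also had a ripple farther out. At its low and high points, 410 and 480 bp from the trough, the wild-type mean was 1.14 and 1.24. At those positions, picked in wild type, the mean was 1.24 and 1.15 in the deletion and 1.24 and 1.17 in H3K56Q.

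**Figure D3:**
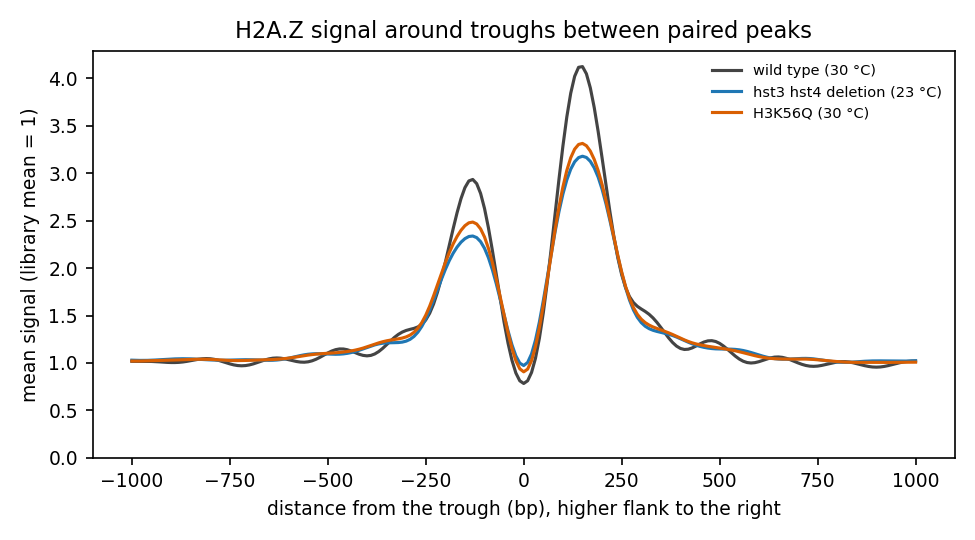
Mean signal (y axis, library mean of 1) by distance in bp from the trough (x axis) over 2293 pairs of peaks, turned so that the higher flank is at the right. Wild type has the highest flanks, 4.12 and 2.93, and the lowest trough, 0.784, against 0.973 in the deletion and 0.907 in H3K56Q.

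Single regions were named by a rule on size and position. Among 1605 regions over 20 kb from a chromosome end, at or above the median level and of the same sign in both mutants, the 8 lowest and 8 highest were taken for each mutant. Because they were picked as extremes of these same ratios, their folds tend to overstate the difference. The intervals given for them do not cover that choice. The 8 lowest of the deletion ranged from 0.529 to 0.686 of wild type. The lowest was R596, on chromosome 4 from 507614 to 507766, with 2.93 in wild type, 1.55 in the deletion and 2.04 in H3K56Q, 0.529 of wild type in the deletion (exact interval 0.435 to 0.64). R2131, on chromosome 10 from 658194 to 658813, had 3.27 in wild type, 2.22 in the deletion and 1.98 in H3K56Q. R1961, on chromosome 10 from 164921 to 165127, had 4.27, 2.80 and 3.02. R208, on chromosome 2 from 467087 to 467429, had 2.96, 1.93 and 2.19.

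The 8 lowest of H3K56Q ranged from 0.362 to 0.559 of wild type. None of them was among the 8 lowest of the deletion, though all were lower there too, as the rule required. R2679, on chromosome 12 from 1013199 to 1013399, had 3.73 in wild type, 3.05 in the deletion and 1.35 in H3K56Q, 0.362 of wild type in H3K56Q (0.314 to 0.416). R3572, on chromosome 15 from 936237 to 936403, had 3.67, 2.52 and 1.82. Its log2 ratio in the deletion, -0.5336, only just missed that of R954, -0.5346, the last of the 8 lowest there. R2726, on chromosome 13 from 99298 to 99949, had 3.61, 2.79 and 2.02. R822 and R823 lie within 3 kb of each other on chromosome 4, starting at 1233421 and 1236063, and had 0.557 and 0.555 of wild type in H3K56Q.

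At the upper end, 2 regions were among the 8 highest of both mutants. R3560, on chromosome 15 from 903096 to 903307, had 1.43 in wild type, 2.17 in the deletion and 3.20 in H3K56Q, which is 1.52-fold (1.28 to 1.79) and 2.24-fold (1.95 to 2.57). R2855, on chromosome 13 from 504302 to 504806, had 1.65, 2.43 and 2.59, which is 1.47-fold (1.33 to 1.63) and 1.57-fold (1.43 to 1.71). R2307, on chromosome 11 from 430126 to 430363, was 2.26-fold higher in H3K56Q (2.00 to 2.57) and 1.14-fold in the deletion (0.963 to 1.34), an interval that includes no difference.

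The log2 ratios of both mutants were compared across regions, which are not independent replicates. Pearson's r was 0.59 and Spearman's rho 0.59, and 79.6% of regions had the same sign. With most regions lower in each mutant, many share a sign without any link between the ratios. Both ratios share the wild-type library, and draws with counting error alone gave an r of 0.44. The covariance was 0.0248 against 0.00219 in those draws. Of the regions lower by 1.5-fold, 4 were shared where independent lists of 14 and 72 would share 0.257, and of those higher, 10 were shared where lists of 15 and 52 would share 0.199. Part or all of this excess may come from the shared wild-type library, which independent lists leave out. Taking H3K56Q as the common reference gave a higher r of 0.66 with a covariance of 0.0295, and taking the deletion gave 0.22 with 0.00778. The share of regions with the same sign was then 59.2% and 61.2%.

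Chromosome ends differed by side. Over the outermost 20 kb, leaving out stretches without reads and segments in which 1 library lay below 0.4 of another, all 16 left ends were higher in the deletion than in wild type, with a median log2 ratio of 0.23, and 12 of 16 in H3K56Q, with 0.26. Of the 15 right ends with usable positions, 6 were higher in the deletion and 6 in H3K56Q, with medians of -0.090 and -0.019. The positions used came to 186 kb of left ends and 162 kb of right ends, unevenly spread over the ends. The highest left ratios in the deletion, 0.76 on chromosome 10 and 0.70 on chromosome 9, rested on 1.69 and 6.12 kb. Wild-type signal there was only 0.183 and 0.151. The lowest left ratio, on chromosome 1, was 0.0095. The segments left out by their ratio came to 26.2 kb of left ends and 2.80 kb of right ends. With them kept the left medians were 0.24 and 0.29. With the median outside regions set equal, 12 of 16 left ends were higher in the deletion, with a median of 0.11, and 2 of 15 right ends. The rise was not confined to 20 kb. From 20 to 30 kb, left sides were 1.09-fold of wild type in the deletion and 1.07-fold in H3K56Q. Right sides there were 0.953-fold and 0.959-fold. Over 50 kb from the ends, mean signal was 1.05 in wild type, 1.05 in the deletion and 1.04 in H3K56Q.

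**Figure D4:**
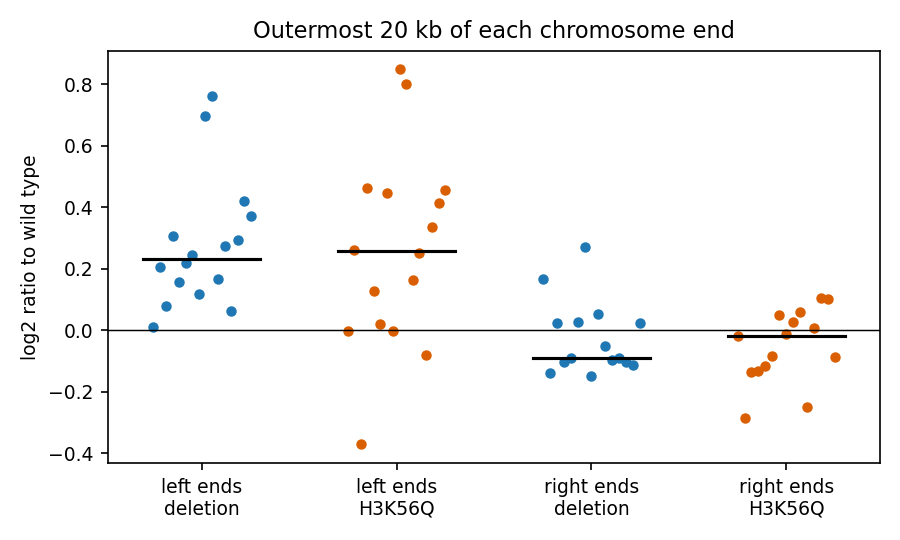
Log2 ratio of mean signal to wild type (y axis) over the usable positions in the outermost 20 kb of each chromosome end, by side and mutant (x axis). Each point is 1 end, whose usable length varies, and the black line is the median. Left ends have medians of 0.23 and 0.26, right ends of -0.090 and -0.019.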

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

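All comparisons in this part with segments covered in a single library, with the segments taken apart, with region length, with a blur of wild type, with temperature and between chromosome sides were chosen after seeing the data. The tests of the residual profile, of 1-kb windows and of left-end profiles were set before their results were seen, but how the first and last of these were read against their spread was decided afterwards.

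Some sequence had signal in H3K56Q at places where wild type was at 0, which were left out of the comparisons. Mean H3K56Q signal was taken over the runs of at least 250 bp at 0 in wild type, not over the short gaps between them. It was 0.867 for runs on chromosome 14 from 765456 to 779146 and 0.427 on chromosome 13 from 917222 to 924251. It was 0.922 on chromosome 9 from 322391 to 323822 and 0.734 on chromosome 8 from 93294 to 94944. On chromosome 4 it was 0.355 from 383676 and 0.422 from 437170. The deletion library was at or near 0 there as well. The H3K56Q library thus holds sequence that the other libraries lack, besides the labelled substitution, and comparisons with it carry that difference. Region R1549, on chromosome 7 from 990309 to 990513, was the only region past 1.5-fold in opposite directions, with log2 ratios of -1.01 in the deletion and 0.96 in H3K56Q, and this difference was not tested.

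Residual signal remained in the segments low in the deletion library, at 14.2% and 17.7% of wild type, and in those low in H3K56Q, at 12.9% together, whose sources were not tested. For the deletion, reads from the H3K56Q library or strain are argued against: in the longest segment covered only in H3K56Q, chromosome 14 from 765301 to 775250, the deletion library held 0.515% of the H3K56Q signal. Reads from wild-type cells or from the wild-type library would follow the wild-type profile, and over 39 windows of 50 bp r was 0.19 (counting interval -0.076 to 0.36), where draws from a wild-type share gave 0.71 (0.50 to 0.85). The value met the bound set to exclude that source, an r under 0.2, but its interval passes it. Apart, r was -0.50 (-0.58 to 0.12) on chromosome 4 and 0.20 (-0.18 to 0.39) on chromosome 15. These counting intervals were drawn around counts that already hold counting error, so they are not confidence intervals of r. Draws from a wild-type share gave 0.64 (0.24 to 0.87) on chromosome 4 and 0.42 (0.023 to 0.72) on chromosome 15. The chromosome 4 value lies below its draws, which argues against wild-type reads as the sole source there. On chromosome 15 they stay open. If part of the residual is a wild-type share, the differences of the deletion library from wild type would be understated: with the whole residual subtracted as such, the median log2 ratio of regions was -0.14.

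The contrast of regions to positions outside them was smaller in both mutants. A coarser resolution of the mutant tracks would leave the means of long regions nearly unchanged. The 985 longest had median log2 ratios of -0.11 in the deletion and -0.10 in H3K56Q, against -0.094 and -0.076 in the 984 shortest. This covers region means and not single peaks. By their highest smoothed point, regions had medians of -0.33 and -0.28. A coarser resolution would also give such a larger drop, so it stays open at that scale. An even background added to both mutants would give a straight line over 1-kb windows, and windows of level 2 or more lay below it by log2 ratios of -0.043 in the deletion and -0.057 in H3K56Q, of observed ratios of -0.099 and -0.11, so such a background may account for part but not all. Growth at 23 °C cannot account for the median of -0.10 in H3K56Q, grown at 30 °C, but stays open for the deletion. A box blur of wild type to the flank height of the mutants would put the trough at 1.56 and 1.43, against 0.973 in the deletion and 0.907 in H3K56Q, so blur of that shape alone does not give the mean profile, and other shapes were not tested. Read extent, 90 bp in wild type against 50 and 54 bp in the mutants, follows the same split and stays open. Smoothing made its width equal, but read placement could not be checked. All libraries are of H2A.Z, so digestion, nucleosome occupancy and precipitation cannot be told from a change of H2A.Z. Strain background and the acetyl-mimicking or constitutively acetylated state itself were not tested and stay open.

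The high-copy segment on chromosome 12 from 459729 to 460637, left out of the comparisons, was 2.29-fold higher in the deletion (2.26 to 2.31) and 2.53-fold in H3K56Q (2.51 to 2.56), its 10-kb flanks were 2.08-fold and 2.02-fold higher in the deletion and 2.32-fold and 2.52-fold in H3K56Q, and left chromosome ends were higher in both. A change tied to distance from a chromosome end on either side would raise right ends too, whose medians were -0.090 in the deletion and -0.019 in H3K56Q. On the left side alone the rise did fall with distance. It went from 1.23-fold within 10 kb to 1.05-fold at 30 to 50 kb in the deletion, and from 1.18-fold to 1.05-fold in H3K56Q. Placement of reads from sequence repeated at several ends may contribute. In wild type 12.3% of the positions in the outermost 20 kb of left ends were at 0, against 36.7% of right ends. The sides differed alike in the deletion, with 17.7% and 42.6%, and in H3K56Q, with 12.1% and 35.4%. These shares therefore do not separate the mutants from wild type. The test of that placement did not decide, since profiles of raised segments at 7 left ends correlated at a median of 0.689, with the 21 pairs ranging from 0.486 to 0.967: this met the bound set against that source, being no higher than the 0.755 of random interior segments, but those reach 0.97 by themselves, so a shared profile would not stand out. That test took the longest raised segment of each left end and shifts of up to 1500 bp, so segments at unlike distances were paired. On chromosomes 4, 7, 12, 13 and 15 they began at 6001, 6401, 6451, 6051 and 7251. On chromosomes 10 and 16 they began at 13751 and 18001. Sequence repeated at like distances from the end could give such alike starts, but whether these segments share sequence was not checked. Copy number of the repeated sequence was not tested and stays open.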

How the results depend on the processing

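No paired analysis was possible because each group has 1 library, and none could be left out. The settings fixed before the data were examined were applied to regions, which were chosen afterwards, and the scaling also to chromosome ends. Those that need gene positions were not run: gene bodies set equal, the narrower window, non-overlapping windows, the later gene body, and every setting for gene lists and named genes. Of 96 values, 70 have a sign and 26 are counts of regions. No sign reversed among the 70 or among the 192 of named regions, of which 170 stayed within counting error and 22 moved. For some settings a reversal was not possible, so the kept signs say nothing there. Another pseudocount keeps the sign of a region's ratio to wild type, and subtracting a wild-type share only moves that ratio away from 0. Named regions were picked as extreme in the same libraries, so a kept sign says little there. R3118, among the highest of the deletion, fell from a log2 ratio of 0.41 to 0.019 with the highest smoothed point. Of all 96, 45 stayed within counting error or 1.5 times the count, and 51 did not. For each shift below the cause was not tested. Values are given for the deletion and then H3K56Q. With values as deposited the median log2 ratio of regions was -0.13 and -0.11, and that of right chromosome ends -0.099 in the deletion. With a pseudocount of 0.01 it was -0.12 in the deletion, with differences in local contrast of -0.20 and -0.16. With 0.2 the medians were -0.11 and -0.094, the contrasts -0.18 and -0.14, and 15 regions passed 1.5-fold in the deletion against 29. With the highest point of the signal smoothed over 75 bp the medians were -0.33 and -0.28, the contrasts -0.40 and -0.33, 363 and 312 regions passed against 29 and 124, and the correlation of both mutants was 0.64. With regions at or above the first quartile of level, a smaller set, the medians were -0.13 and -0.11, the contrasts -0.21 and -0.18, and 13 and 70 passed.

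The other settings were chosen after seeing the data. With the median outside regions set equal the medians were -0.24 and -0.18 and 66 passed in the deletion, where 60 were lower and 6 higher against 14 and 15. Left chromosome ends then had medians of 0.11 and 0.17 and right ends of -0.21 and -0.10. With the segments left out by their ratio kept, left ends had 0.29 in H3K56Q, and no value of regions moved past those limits. With tracks smoothed to a common read extent the medians of regions were -0.13 and -0.11. A region threshold of 2 gave medians of -0.16 and -0.14 and contrasts of -0.22 and -0.18. A gap of 150 bp gave -0.13 and -0.11, contrasts of -0.21 and -0.17, and 51 passing in the deletion. Regions called in H3K56Q alone gave -0.11 and a contrast of -0.19 in the deletion. A further setting treated the residual of the depleted segments as a wild-type share, a source not settled for either mutant. With it subtracted the medians were -0.14 and -0.12, the contrasts -0.23 and -0.18, and 66 and 193 passed. Depth limited single regions most in the deletion, with a median of 634 reads per region against 1137 in wild type.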

Other observations

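A 10-kb stretch of chromosome 13, from 362801 to 372800, had a mean signal of 2.77 in H3K56Q, 1.03 in wild type and 0.999 in the deletion, so that H3K56Q was 2.70-fold above wild type. On chromosome 15 from 3351 to 11150 the deletion had 1.84 and H3K56Q 1.76, against 0.837 in wild type. On chromosome 7 from 957651 to 960600 H3K56Q had 1.01, wild type 0.536 and the deletion 0.684. On chromosome 2 from 623801 to 625950 the values were 1.68, 1.02 and 1.07. On chromosome 7 from 15951 to 18050 H3K56Q had 1.99, wild type 0.973 and the deletion 1.36. Beside the high-copy segment of chromosome 12, from 449801 to 456450, the deletion had 1.05, H3K56Q 1.06 and wild type 0.5, and from 461651 to 468600 the values were 0.821, 0.981 and 0.383. These stretches were picked by their values. Without an input library, more DNA copies cannot be told from more H2A.Z there.

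Chromosome 12 differed most from the other chromosomes in the deletion. Over positions outside regions and over 20 kb from the ends, the log2 ratio per chromosome ran from 0.043 to 0.15 in the deletion and from -0.0057 to 0.11 in H3K56Q. The 0.15 was that of chromosome 12, and the next highest was 0.099 on chromosome 15. Its region median in the deletion, -0.055, was also the nearest to 0, with -0.096 next on chromosome 16. In H3K56Q chromosome 12 had 0.105 outside regions, after 0.115 on chromosome 11, and its region median, -0.069, was the nearest to 0. Wild type, which both ratios share, had its lowest chromosome mean there, 0.991. Peaks beside a trough were set against other peaks at matched level. For level 3 to 4 the medians were -0.24 for 1236 paired and -0.23 for 659 unpaired peaks in the deletion, and -0.19 and -0.18 in H3K56Q. For level 1.5 to 2 they were -0.092 and -0.023 in the deletion and -0.030 and -0.040 in H3K56Q.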
